A study of Mus musculus with 24 samples.

How the data were processed

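RNA of primary muscle cells from the quadriceps of ICR mice was measured on 24 single-colour expression arrays, 1 array per sample. The cells came from offspring of control dams and of dams whose food was restricted during pregnancy. Both kinds of culture were kept either in a standard differentiation medium or, overnight, in a medium poor in glucose and other substrates, which gave 4 groups of 6 arrays. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by the WT PLUS procedure.

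The deposited table holds 1 value per array for 41345 transcript clusters, a transcript cluster being the set of probes that an array assigns to a locus. Per the submitters' processing notes, the values were made with RMA (background correction, quantile normalization between arrays and summary by median polish) in Affymetrix Expression Console. The versions of these tools, the genome build behind the clusters and whether all arrays were processed as a set are not given in the sources used here. The deposited values were read as log2 signal: they ran from 1.69 to 14.1 with array medians from 5.60 to 5.81, the range RMA gives on a log2 scale, but the base of the logarithm itself is not stated. No detection calls were used, and the number of arrays limits the precision. No pair of arrays held identical values, and the highest correlation between any pair was 0.995.

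Clusters were named through a table of the platform's annotation, with symbols updated by Entrez identifier through a RefSeq gene table (assembly GRCm38.p6), in which 23328 of the clusters with exactly 1 symbol had their gene. Of all clusters, 23521 had exactly 1 gene symbol, 1814 had several and 16010 are not named here. Clusters with several symbols or none stayed out of the gene tests. For the 1082 genes with more than 1 cluster, the cluster with the highest mean over all arrays was used, which left 22180 genes. Dim genes were not filtered out.

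Each gene was tested with limma (version 3.58.1, in R 4.3.3), using lmFit and eBayes on the log2 values of all 24 arrays in 4 groups with a shared estimate of the spread. The contrasts were the medium effect (limited minus standard) over both maternal diets and within each, the maternal diet effect (undernourished minus control) in each medium, and the difference of the medium effect between maternal diets. For the maternal diet effect over both media, both arrays that carry a culture number were averaged first and 6 cultures were compared with 6. All tests were two-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05 on the adjusted p. Errors of differences are standard errors from these fits, and errors of group levels are SD over 6 arrays.

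The design, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, for each comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall whose mean in the higher group was at or above 6.02, the median of all tested genes. Model, clone, small RNA and receptor-family symbols were counted and not named. Up to 4 called members of each gene list were named as well. Where fewer than 5 genes were called, the 5 genes with the smallest p in each direction were named as not past the threshold. Other members of a list are named where the list is described.

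There were 39 gene lists of pathways and of cell type markers, with 765 entries, of which 692 were measured; 37 lists had measured members. The lists of mitochondrially encoded and erythroid genes had none. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, with adjustment over the 37 lists of a comparison. A permutation test of each list's mean over arrays or cultures was added after the data had been seen. It shuffled the medium within maternal diets 100000 times for the effect over both diets and enumerated all regroupings exactly elsewhere. For the medium effects it moved arrays without regard to the culture number, so it did not test lists within cultures. The smallest p of the exact test is 0.00216, or 0.0801 after adjustment where 1 list alone reaches it, so a single list cannot pass by it.

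The labels give a number to each culture and do not say whether it stands for an animal, a litter or a flask, so directions and responses per culture only compare the arrays that carry the same number, and p-values measure the spread between these samples, part of which may be technical. A second number in the titles, from 1 to 24, has no stated meaning and was tried as a covariate.

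The procedure was tested on simulated data with 22180 genes and changes put into some of them. In the medium effect over both diets it recovered 82.1% of genes changed by 0.5 on the log2 scale and 97.0% of those changed by 1. For the maternal diet effect the recovery at 0.5 was 58.2% in standard medium, 74.6% in limited medium and 85.1% over both media. For the difference of the medium effect it was 28.4% at 0.5 and 92.5% at 1. Noise was drawn independently for each gene and array, also for arrays of the same culture number. If such arrays correlate in the real data, the recovery over both media is too high. Each comparison was simulated once, with 67 genes changed by 0.5, so the values in standard and limited medium may differ by the draw.

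The alternatives tried were the culture number as a block, a filter on dim genes, quantile normalization and median centring of the deposited values, averaging the clusters of a gene, eBayes with a mean-variance trend and robust settings, array quality weights, only the groups compared in the fit, the title number as a covariate, other thresholds, and leaving out each culture in turn. Leaving out each culture in turn in the list tests, leaving out cultures 16 and 20 together and removing a trend with gene length were added after the data had been seen. A list of nuclear-retained RNAs was also added then, for the tests of the length trend.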

Results

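The 24 arrays cover primary cells isolated from mouse quadriceps, grown and then differentiated into myotubes. In the undernourished group the dams received 50% of the food of matched controls from day 12.5 of gestation, and litters of both groups were equalized to 8. The standard medium held 5.5 mM glucose and 2% fetal bovine serum. The limited medium, applied overnight, held 0.5 mM glucose, 1 mM glutamine, 0.5 mM carnitine and 1% serum. Each combination of maternal diet and medium had 6 arrays. The design sets the offspring of undernourished dams against controls and asks how their cells respond to scarce substrate.

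The cultures carried the transcripts of differentiated muscle. The markers of differentiated myotubes averaged 11.96 ± 0.06 in control standard arrays (log2 signal, SD, n = 6) and those of satellite cells and myoblasts 8.51 ± 0.03. Markers of other cell types lay lower in the same group, at 5.51 ± 0.24 for fibroblasts and fibro-adipogenic progenitors, 5.41 ± 0.08 for endothelial cells, 5.26 ± 0.04 for macrophages and other leukocytes, 6.82 ± 0.10 for smooth muscle and pericytes, 5.07 ± 0.06 for adipocytes, 5.48 ± 0.28 for Schwann and glial cells and 5.72 ± 0.14 for tenocytes. Probes differ in brightness, so these means are not proportions of cells. Xist, expressed from an inactive X chromosome, lay between 9.87 and 11.5 on all arrays, and the Y-linked genes Eif2s3y, Uty and Kdm5d between 2.95 and 3.99. Cultures differed in collagen and glial transcripts, read from genes chosen after their values were seen. Col1a1 averaged 11.52 in undernourished culture 20, 10.67 in control culture 16 and 9.00 in control culture 24, and the lowest culture had 7.07. The glial gene Cdh19 averaged 9.90 in culture 20, 6.21 in culture 16 and 5.99 in culture 24, and the lowest culture had 3.44.

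In limited medium, 17 of 19 chaperone and quality-control genes of the endoplasmic reticulum, called chaperones below, rose. In the same medium, 9 of 15 genes of cholesterol synthesis and uptake and 5 of 13 of fatty acid synthesis fell. As lists these had adjusted p = 0.123, 0.467 and 0.546 with an estimated correlation. Over both maternal diets, the largest rises at an adjusted p under the threshold were in Sdf2l1, a component of the chaperone machinery of the endoplasmic reticulum (log2 difference 1.7 ± 0.23 SE, a 3.24-fold rise), and Creld2, a stress-inducible protein of the same compartment (1.63 ± 0.18). Sdf2l1 averaged 8.07 ± 0.59 in control standard and 9.45 ± 0.69 in control limited arrays, and 7.92 ± 0.23 and 9.93 ± 0.82 in the undernourished groups (SD, n = 6). The largest fall was in Txnip, a glucose-responsive inhibitor of thioredoxin, which fell by 1.46 ± 0.20 on the log2 scale and was lower in limited medium in 12 of 12 cultures. It averaged 7.52 ± 0.54 and 6.30 ± 0.43 in the control groups and 7.77 ± 0.81 and 6.08 ± 0.16 in the undernourished groups.

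The other genes with the largest rises were Derl3 (1.43 ± 0.27) and Herpud1 (1.29 ± 0.17), both of the degradation pathway of the endoplasmic reticulum, the oxidoreductase Ero1b (1.24 ± 0.19), the inducible heat shock gene Hspa1b (1.39 ± 0.29), the cystine transporter Slc7a11 (1.33 ± 0.33), the stress transcription factor Ddit3, also called CHOP (1.31 ± 0.23), the RNA-binding protein gene Rbm15b (1.34 ± 0.19) and the peptidylarginine deiminase Padi2 (1.23 ± 0.25). Each was higher in limited medium in 10 or more of 12 cultures. Hspa1b and its copy Hspa1a are nearly identical, so the signal of either gene is uncertain. After Txnip the largest falls were in the imprinted gene Mest (-1.08 ± 0.32), the fatty acid elongase Elovl6 (-1.05 ± 0.19), the connexin Gjd4 (-1.01 ± 0.27), Gadd45g (-1.01 ± 0.16), Gca (-0.99 ± 0.11), the arrestin-domain gene Arrdc3 (-0.97 ± 0.19), Pmp22 (-0.93 ± 0.18), the sterol dehydrogenase Nsdhl (-0.91 ± 0.15) and the transporter gene Slc38a6 (-0.88 ± 0.14).

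**Figure D1:**
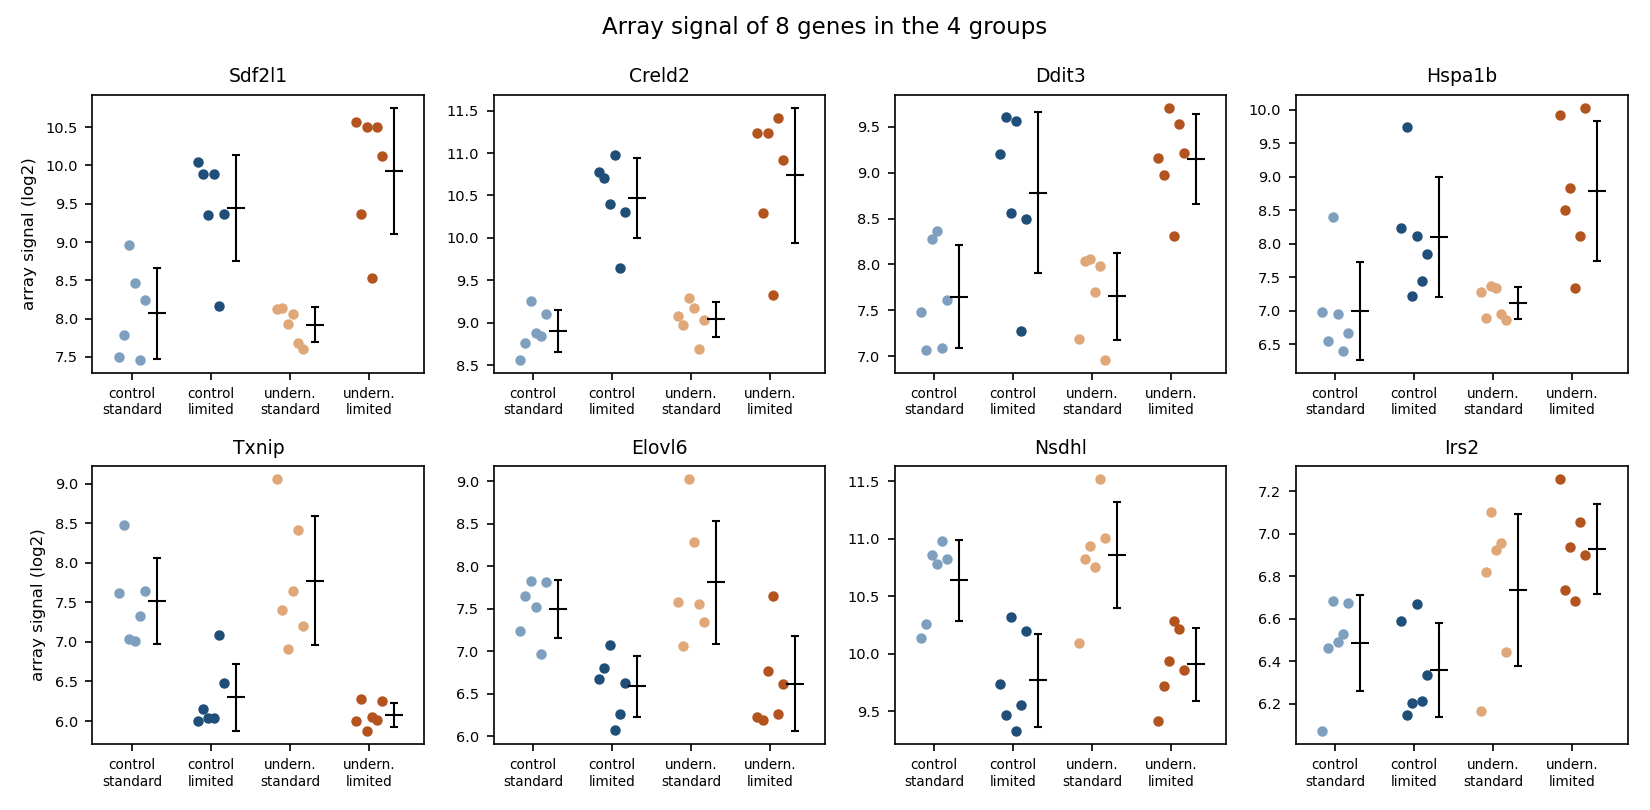
Log2 array signal (y axis) of 8 genes on each array of the 4 groups of maternal diet and medium (x axis; undern., undernourished), with 6 arrays per group as points and the mean ± SD as a bar. Sdf2l1 averaged 8.07 in control standard and 9.45 in control limited arrays, and Txnip 7.52 and 6.30.

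Of 19 measured chaperones and quality-control genes of the endoplasmic reticulum, 17 rose and 2 did not pass, and 17 rose when adjusted over the list alone. The risen members included Syvn1, a ubiquitin ligase (1.15 ± 0.17), Hspa5, the central chaperone of the compartment (0.87), and Hsp90b1 (0.76). Camera placed the list above other genes (adjusted p = 2.16e-25), as did the permutation of arrays (adjusted p = 0.00129), with adjusted p = 0.123 with an estimated correlation. Of 33 measured integrated stress response genes, targets of ATF4 and CHOP, 12 rose and none fell; adjusted over the list alone, 20 rose and 1 fell. They included the pseudokinase Trib3 (1.21 ± 0.23) and Chac1, which degrades glutathione (1.08 ± 0.20), while the asparagine synthetase Asns differed by 0.09. Camera gave an adjusted p of 4.07e-13 for the list and the permutation 0.0314, with adjusted p = 0.467 with an estimated correlation.

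Of 15 measured genes of cholesterol synthesis and uptake, 9 fell and 1 rose (11 and 1 adjusted over the list alone). Besides Nsdhl, the sterol oxidase Msmo1 fell by 0.58 ± 0.11, the squalene epoxidase Sqle by 0.53 ± 0.14 and the demethylase Cyp51 by 0.51 ± 0.15. The list was lower by camera (adjusted p = 3.57e-07) and by permutation (0.0209), with adjusted p = 0.467 with an estimated correlation. Of 13 genes of fatty acid synthesis, 5 fell (6 adjusted over the list alone), among them the desaturases Fads2 (-0.63 ± 0.16) and Fads1 (-0.54 ± 0.13) and the elongase Elovl5 (-0.37 ± 0.09). Camera called this list lower (adjusted p = 0.00882), the permutation did not (0.0663), and adjusted p = 0.546 with an estimated correlation. Of the 3 measured MondoA targets, which are induced by glucose, Txnip alone fell (2 adjusted over the list alone), with adjusted p = 0.00772 by camera, 0.00129 by permutation and adjusted p = 0.322 with an estimated correlation.

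Nuclear genes of oxidative phosphorylation were slightly higher in limited medium, with 11 of 57 risen (17 adjusted over the list alone) and a median difference of 0.18. The largest rises were in the cytochrome oxidase subunit Cox7a1 (0.74 ± 0.18) and the ATP synthase subunit Atp5e (0.45 ± 0.11), and Cyc1 (0.37 ± 0.08) and Cox4i1 (0.34 ± 0.08) rose as well. Camera gave the list an adjusted p of 4.77e-11 and the permutation 0.0385, with adjusted p = 0.508 with an estimated correlation. Of 25 genes of fatty acid oxidation, 4 rose (5 adjusted over the list alone): the acyl-CoA thioesterase Acot2 (1.08 ± 0.24), Acaa2 (0.55 ± 0.11), Acadvl (0.29 ± 0.07) and the carnitine acetyltransferase Crat (0.28 ± 0.07). Of 20 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, Pdk2 (0.45 ± 0.12), Mdh1 (0.34 ± 0.09) and Idh3g (0.25 ± 0.07) rose, and 4 rose and 1 fell adjusted over the list alone. For both lists camera called a rise (adjusted p = 0.0438 and 0.0437), the permutation did not (0.075 and 0.139), and adjusted p = 0.559 and 0.579 with an estimated correlation. Both camera calls ended without control culture 5, 24 or 11 or undernourished culture 8, 4, 20 or 12, with adjusted p from 0.052 to 0.179. In the list of mitochondrial biogenesis, which camera did not call (adjusted p = 0.2), Twnk (0.30 ± 0.07) and Esrra (0.25 ± 0.06) rose and the coactivator Ppargc1b fell by 0.53 ± 0.08, with the same counts adjusted over the list alone.

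Of 26 measured imprinted genes, 7 fell and none rose (8 fell adjusted over the list alone). Besides Mest they included the growth regulator Plagl1 (-0.57 ± 0.17), Sgce (-0.47 ± 0.09) and Airn (-0.45 ± 0.08), a noncoding RNA that overlaps Igf2r on the opposite strand. The list was lower by camera (adjusted p = 0.00016) and by permutation (0.0021), with adjusted p = 0.0886 with an estimated correlation. Of 18 p53 targets, Sesn2 (0.77 ± 0.17), Eda2r (0.44 ± 0.10) and the death gene Bbc3 (0.29 ± 0.08) rose and Trp53inp1 fell by 0.37 ± 0.10; 5 rose and 1 fell adjusted over the list alone. Sesn2 is also in the integrated stress list. The list was higher by camera (adjusted p = 0.0206) and permutation (0.0385), with adjusted p = 0.508 with an estimated correlation.

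Of 15 markers of differentiated myotubes only the creatine kinase Ckm rose (0.47 ± 0.12), also when adjusted over the list alone, and 13 were higher. The list passed camera (adjusted p = 0.0275) and the permutation (0.0152), with adjusted p = 0.467 with an estimated correlation. In the contractile apparatus, 2 of 42 rose, Ckm and the troponin Tnni2 (0.49 ± 0.11), 2 also adjusted over the list alone. Of 21 genes of ribosome biogenesis, Bop1 (0.29 ± 0.07) and Rrp9 (0.24 ± 0.06) rose, with 4 risen and 1 fallen adjusted over the list alone, and none of 26 cell cycle genes passed either way. Camera called the contractile and ribosome biogenesis lists higher (adjusted p = 0.01 for both) and the cell cycle list lower (0.0198). The permutation, which ignored the culture number, called none of these lists (adjusted p = 0.0699, 0.165 and 0.227), and adjusted p = 0.559, 0.559 and 0.654 with an estimated correlation. Leaving out 1 undernourished culture ended the camera call of the myotube list (culture 8, adjusted p = 0.0566), of ribosome biogenesis (culture 9, 0.0801) and of the cell cycle list (culture 4, 0.226).

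The remaining lists were called neither by camera nor by permutation, and single members passed over all genes. In glycolysis and glucose uptake, of 18 genes the phosphofructokinase Pfkm rose by 0.43 ± 0.11, and Pfkl (-0.60 ± 0.15), Pgam1 (-0.36 ± 0.09) and Pfkfb3 (-0.25 ± 0.07) fell. Of 16 circadian clock genes, Arntl (0.41 ± 0.08), Ciart (0.40 ± 0.12), Nr1d2 (0.37 ± 0.10) and Per1 (0.36 ± 0.10) rose and 1 fell. Of 19 immediate early and serum response genes, the transcription factor Srf rose by 0.59 ± 0.07, while Egr1 (-0.72 ± 0.15), Ccn1 (-0.52 ± 0.14) and Fos (-0.37 ± 0.10) fell. Among insulin and IGF signalling genes, the receptor Igf1r (-0.60 ± 0.12) and its ligand Igf1 (-0.30 ± 0.08) fell. The chromatin genes Tet2 (-0.55 ± 0.12) and Hdac9 (-0.51 ± 0.10), the collagen-modifying enzymes P4ha1 (-0.45 ± 0.10) and Plod2 (-0.39 ± 0.09), the interferon-response genes Stat2 (-0.46 ± 0.11) and B2m (-0.28 ± 0.08) and the hypoxia factor Hif1a (-0.25 ± 0.07) fell, P4ha1 being in the hypoxia list too. In the inflammatory list Ptgs2 rose by 1.04 ± 0.28 and Vcam1, also a satellite cell marker, fell by 0.45 ± 0.10. Klf15 (0.35 ± 0.08) rose and Trp53inp1 fell in the FOXO list, Map1lc3a rose in the autophagy list (0.50 ± 0.11), Hmox1 in the NRF2 list (0.61 ± 0.19) and the tendon gene Scx in the tenocyte list (0.46 ± 0.11). Adjusted over the list alone, glycolysis had 2 risen and 3 fallen genes, the FOXO list 3 and 2, the clock 5 and 2, hypoxia 1 and 5, insulin and IGF signalling 1 and 2 and NRF2 1 and 1, and the other lists of this paragraph kept their counts. Camera's adjusted p over these lists lay between 0.0626 and 0.997. For glycolysis, myogenic regulators, the inflammatory list, endothelial cells, leukocytes and sex-linked genes the median, the mean and the camera direction did not all share a sign. No member of the lists of myogenic regulators, fibroblasts, endothelial cells, leukocytes, smooth muscle, adipocytes, glia or sex-linked genes passed, and their median differences lay between -0.06 and 0.04.

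In all, limma called 1517 of 22180 genes for the medium over both diets, 790 higher and 727 lower, and 30 of them differed by at least 1 on the log2 scale. With camera at the preset correlation 14 lists passed, with the permutation 8, and with an estimated correlation 0. Among the 11044 genes with a known genomic span and a level at or above the median, 64 of the 967 in the shortest class rose and 19 fell, and of the 1382 in the longest class 37 rose and 149 fell. The count was 991 without control culture 5 and 996 without undernourished culture 4. It was 2325 at an adjusted p under 0.1 and 267 with a difference of at least 0.5.

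**Figure D2:**
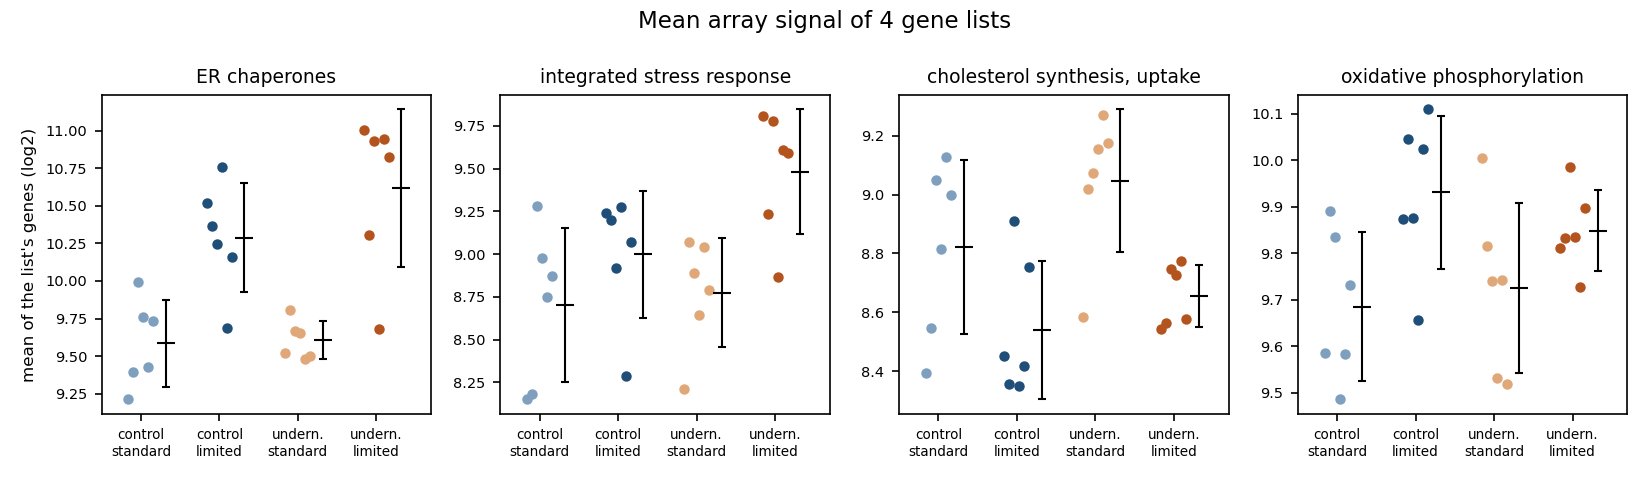
Mean log2 signal (y axis) over the measured genes of 4 lists on each array of the 4 groups (x axis; undern., undernourished), with 6 arrays per group as points and mean ± SD as a bar. The endoplasmic reticulum chaperones averaged 9.59 and 10.29 in control standard and limited arrays and 9.60 and 10.62 in the undernourished groups.

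Within control cultures, limited medium raised Creld2 by 1.56 ± 0.26 and Herpud1 by 1.08 ± 0.24, the only 2 of 19 chaperones past the threshold over all genes, whereas 17 passed adjusted over the list alone. The RNA helicase Ddx5 fell by 1.08 ± 0.15, from 11.63 ± 0.36 to 10.55 ± 0.19 (SD, n = 6), Gadd45g by 1.01 ± 0.23, Gca by 0.96 ± 0.16, the cell cycle kinase Cdk6 by 0.81 ± 0.17, Ogn by 0.76 ± 0.15, the antizyme inhibitor Azin1 by 0.72 ± 0.10, Lpp by 0.70 ± 0.15, Tmem175 by 0.60 ± 0.09, and Cnot6 and Trmt5 each by 0.59. The other large rises were Ndrg4 (1.26 ± 0.28), the acyltransferase Agpat2 (1.09 ± 0.16), Scx (0.74 ± 0.15), Ubald1 (0.72 ± 0.15), the citrate transporter Slc13a5 (0.71 ± 0.15), Hs3st3b1 (0.70 ± 0.13), Get3 (0.67 ± 0.15) and Srf (0.66 ± 0.10). Each of these named genes moved in its direction in 6 of 6 cultures.

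Limma called 76 genes in control cultures, 37 higher and 39 lower, and after quantile normalization of the deposited values 31 of 82 called genes were higher. Across the alternatives the share of called genes that were higher ran from 37.8%, after this normalization, to 60.9% without cultures 16 and 20. Camera called 10 lists at the preset correlation, led by the endoplasmic reticulum chaperones (median 0.70, adjusted p = 1.02e-15), oxidative phosphorylation (0.24, 2.34e-15), imprinted genes (-0.19, 0.000132), cholesterol synthesis (-0.39, 0.00018) and the integrated stress response (0.25, 0.000289). None passed with an estimated correlation (adjusted p = 0.508, 0.53, 0.0659, 0.53 and 0.61 in that order) or by exact permutation (lowest adjusted p = 0.172). Adjusted over the list alone, 15 oxidative phosphorylation genes rose, 6 imprinted and 6 cholesterol genes fell, and with limma 0 integrated stress genes passed. The integrated stress median was 0.09 without control culture 5 and 0.16 without culture 24, where its camera call ended (adjusted p = 0.162 and 0.235), and 0.38 and 0.39 without cultures 16 and 11. The cholesterol median was -0.24 without culture 11. The count fell to 10, 49, 24, 20, 30 and 13 without control cultures 5, 24, 16, 15, 11 and 10 and to 50 and 35 without undernourished cultures 8 and 12, and was 162 without undernourished culture 20. It was 149 among genes at or above the median level, 275 with array weights, 253 at an adjusted p under 0.1, 47 with a difference of at least 0.5 and 115 without cultures 16 and 20.

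Within undernourished cultures, the same medium raised Sdf2l1 by 2.01 ± 0.33, a 4.02-fold rise, and 16 of 19 chaperones of the endoplasmic reticulum rose (17 adjusted over the list alone), among them Creld2 (1.7 ± 0.26), Herpud1 (1.5 ± 0.24) and Syvn1 (1.37 ± 0.24). Of 33 integrated stress response genes 9 rose (21 adjusted over the list alone), including Trib3 (1.68 ± 0.33), Ddit3 (1.49 ± 0.33), Chac1 (1.33 ± 0.28) and Atf3 (1.10 ± 0.24). Other large rises were Hspa1a (1.86 ± 0.39), Derl3 (1.82 ± 0.38), Hspa1b (1.67 ± 0.41), Ero1b (1.61 ± 0.27), Acot2 (1.58 ± 0.34), Ptgs2 (1.55 ± 0.40) and Rbm15b (1.51 ± 0.27). Txnip fell by 1.7 ± 0.28, Elovl6 by 1.19 ± 0.27, Gca by 1.02 ± 0.16, Gadd45g by 1.00 ± 0.23, Nsdhl and Slc38a6 each by 0.95, Antxr1 by 0.94 ± 0.22, Frk by 0.91 ± 0.21, and the plasminogen activator Plau and the actin bundler Pls3 each by 0.90. Of 15 cholesterol genes 3 fell, among them the sterol regulator Srebf2 (-0.42 ± 0.11), and adjusted over the list alone 10 fell and 1 rose.

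Limma called 324 genes in undernourished cultures, 161 higher and 163 lower. Camera called 11 lists at the preset correlation, among them the chaperones (median 1.04, adjusted p = 3.32e-29), the integrated stress response (0.67, 2.37e-19), cholesterol synthesis (-0.44, 2.18e-07) and ribosome biogenesis (0.23, 5.91e-05), with adjusted p = 0.149, 0.273, 0.402 and 0.551 with an estimated correlation. By exact permutation the lowest adjusted p was 0.0801, and the smallest p that the regroupings can give, 0.00216, becomes 0.0801 where 1 list alone reaches it. The count was 115, 51, 89 and 75 without undernourished cultures 9, 4, 1 and 12, and 214 without control culture 10. With only the groups compared in the fit it was 59, the same as in control cultures under that fit. It was 571 with array weights and 622 at an adjusted p under 0.1. With a difference of at least 0.5 it was 192, and without cultures 16 and 20 it was 494.

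Cells of both maternal diets moved mostly the same way. All 76 genes called in control cultures had the same direction in undernourished cultures and 44 were called in both in the same direction, against a same-direction overlap of 0.555 expected for independent lists of these sizes. Both lists use the same spread estimate of each gene, which can favour the same genes in both, so independence is a lenient comparison. Of the 324 genes called in undernourished cultures, 317 had the same direction in control cultures. Across genes, which are not independent replicates, the log2 differences of both diets correlated with a Pearson r of 0.602 and a Spearman rho of 0.484.

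The difference of the medium effect asks whether cells from undernourished offspring respond otherwise to scarce substrate. The integrated stress response differed by a median of 0.38 (undernourished minus control response), with 31 of 33 members above 0 (camera adjusted p = 2.98e-08), and the chaperones by 0.25 (7.43e-05). With an estimated correlation both had adjusted p = 0.943, and by exact permutation over cultures the unadjusted p was 0.258 and 0.297. The integrated stress median was 0.20 without control culture 11 and 0.21 without undernourished culture 9. The chaperone median was 0.38 and 0.15 without control cultures 5 and 16, and 0.16 and 0.50 without undernourished cultures 9 and 20. Camera also called oxidative phosphorylation (-0.13, adjusted p = 5.13e-05), ribosome biogenesis (0.18, 0.000468), the cell cycle list (-0.21, 0.00196) and hypoxia targets (0.22, 0.0414), each with adjusted p = 0.943 with an estimated correlation. The cell cycle call rested on undernourished culture 4, without which the median was 0.02 (adjusted p = 0.87). The oxidative phosphorylation median was -0.09 without control culture 11 and -0.08 without undernourished culture 9, where the call ended (adjusted p = 0.0718), and that of ribosome biogenesis was 0.09 and 0.12 without undernourished cultures 9 and 12. The hypoxia call ended without control culture 5, 16, 15 or 10 or undernourished culture 9, 4 or 12, the median being 0.10 without culture 15 and 0.14 without culture 9. The integrated stress list rose in 4 of 6 control cultures (mean 0.30 ± 0.66 SD) and 6 of 6 undernourished cultures (0.71 ± 0.53 SD). With limma, 0 genes passed for this difference, while 643 had an unadjusted p under 0.05 against 1109 expected by chance. The smallest p belonged, without passing, to Cdsn (1.11 ± 0.28), Sh2d6 (0.87 ± 0.28), Tapbpl (0.58 ± 0.18), Trim46 (0.53 ± 0.16) and Slc5a5 (0.37 ± 0.11) among the higher and to Wnt10a (-0.48 ± 0.14), Zfp296 (-0.36 ± 0.11), Med28 (-0.37 ± 0.12), Ciao3 (-0.31 ± 0.10) and Usp46 (-0.55 ± 0.18) among the lower.

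In limited medium, no gene separated the maternal diets at the threshold. The smallest p belonged to Cdsn, corneodesmosin, at 7.25 ± 0.45 in undernourished and 6.17 ± 0.20 in control arrays (SD, n = 6; difference 1.08 ± 0.20, limma adjusted p = 0.316). Also below the threshold were Irs2, an adaptor of the insulin receptor (0.57 ± 0.14), Slc22a23 (0.79 ± 0.20), Sytl2 (0.52 ± 0.14) and Wars2 (0.34 ± 0.10) on the higher side, and Sipa1l2 (-0.39 ± 0.09), Lmo7 (-0.53 ± 0.12), Grhpr (-0.50 ± 0.13), Pbx3 (-0.55 ± 0.14) and Zfp668 (-0.35 ± 0.10) on the lower side. Irs2 passed when adjusted over the list alone, as 1 of 21 insulin and IGF signalling genes and as 1 of 20 FOXO targets. Integrated stress response genes had a median difference of 0.45, with 32 of 33 higher in undernourished arrays (camera adjusted p = 3.07e-16), with adjusted p = 0.668 with an estimated correlation and an exact permutation p of 0.0498 (adjusted 0.596). The chaperones had a median of 0.33, with 19 of 19 higher (camera adjusted p = 3.17e-08; adjusted p = 0.668 with an estimated correlation), and 0.55 without undernourished culture 20. Camera also called oxidative phosphorylation (adjusted p = 0.000645) and collagens (0.0225), both lower in undernourished arrays, and ribosome biogenesis (0.0197), which was higher. Their list means were 9.85, 7.70 and 9.03 in undernourished limited arrays, against 9.93, 8.04 and 8.93 in control limited arrays. With an estimated correlation these calls had adjusted p = 0.757, 0.757 and 0.693. These calls each ended without single cultures: oxidative phosphorylation without control culture 10 (adjusted p = 0.102), ribosome biogenesis without control culture 11 or undernourished culture 9, 4, 1 or 12 (from 0.0527 to 0.243), and collagens without control culture 16 or 15 or undernourished culture 9, 8 or 4 (from 0.0531 to 0.468). On the collagen list cultures 16 and 20 averaged 8.78 and 9.21, against 7.32 to 8.38 in the others. The number of lists called was 5, and 3 and 9 without undernourished cultures 4 and 20. Limma called 0 genes, and 1206 had an unadjusted p under 0.05 against 1109 expected. Cdsn passed with array weights, and Cdsn and Sytl2 passed without undernourished culture 20 (adjusted p = 0.00954 and 0.00575) and without cultures 16 and 20.

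In standard medium, the 26 cell cycle genes were all higher in undernourished arrays, with a median difference of 0.23 (camera adjusted p = 6.8e-08), with adjusted p = 0.936 with an estimated correlation and an exact permutation p of 0.318. This rested on undernourished culture 4, at a list mean of 7.23, without which the median difference was 0.06 and the call ended (adjusted p = 0.315). Camera also called cholesterol synthesis (0.29, adjusted p = 4.95e-05) and contractile genes (-0.07, 0.00152). It called the tricarboxylic acid cycle higher (adjusted p = 0.0129) and myotube markers lower (0.0355) in undernourished arrays. Their list means were 10.23 and 11.86 there, against 10.14 and 11.96 in control standard arrays. Each of these lists had adjusted p = 0.936 with an estimated correlation and 0.94 by exact permutation. The cholesterol median was 0.18 and 0.19 without control cultures 5 and 24, and the contractile median -0.04 and -0.12 without control cultures 24 and 15 and -0.14 without undernourished culture 9, where 8 lists were called in place of 5. Without control culture 11 or undernourished culture 1 the calls of the tricarboxylic acid cycle and of myotube markers ended, and the latter also without control culture 10 or undernourished culture 4 or 20. Limma called 0 genes, 697 having an unadjusted p under 0.05 against 1109 expected. The smallest p belonged to Cibar1 (0.46 ± 0.12), Lancl2 (0.45 ± 0.12), Nxt2 (0.29 ± 0.09), Tmx3 (0.32 ± 0.10) and the glyoxalase Glo1 (0.77 ± 0.24) on the higher side and to Fam222a (-0.32 ± 0.08), Ankrd33b (-0.32 ± 0.09), the muscle kinase Speg (-0.34 ± 0.10), Gp9 (-0.27 ± 0.08) and the clock gene Npas2 (-0.25 ± 0.08) on the lower side.

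Over both media, with 6 cultures against 6, Lmo7 (-0.40 ± 0.07, limma adjusted p = 0.707) and Irs2 (0.41 ± 0.08, adjusted p = 0.707) had the smallest p and did not pass. Irs2 averaged 6.49 ± 0.22 and 6.36 ± 0.22 in control standard and limited arrays and 6.74 ± 0.36 and 6.93 ± 0.21 in the undernourished groups, and it passed when adjusted over the list alone, as 1 of 21 insulin and IGF signalling genes and 1 of 20 FOXO targets. The next were Grhpr (-0.42 ± 0.09), Ep400 (-0.65 ± 0.15), Tppp3 (-0.54 ± 0.13) and Rprl2 (-0.38 ± 0.10) among the lower, and Rpap2 (0.28 ± 0.07), Lmo4 (0.36 ± 0.09), Smim10l1 (0.24 ± 0.06) and Cdsn (0.53 ± 0.14) among the higher. Camera called 7 lists at the preset correlation, led by the integrated stress response (median 0.21, 33 of 33 higher, adjusted p = 6.66e-14), and none passed with an estimated correlation (lowest adjusted p = 0.715) or by permutation (lowest 0.774). The integrated stress median was 0.33 without undernourished culture 20, and the number of lists called was 11 without control culture 16 or 15 or undernourished culture 20 and 4 without undernourished culture 4. Limma called 0 genes, and 791 had an unadjusted p under 0.05 against 1109 expected.

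**Figure D3:**
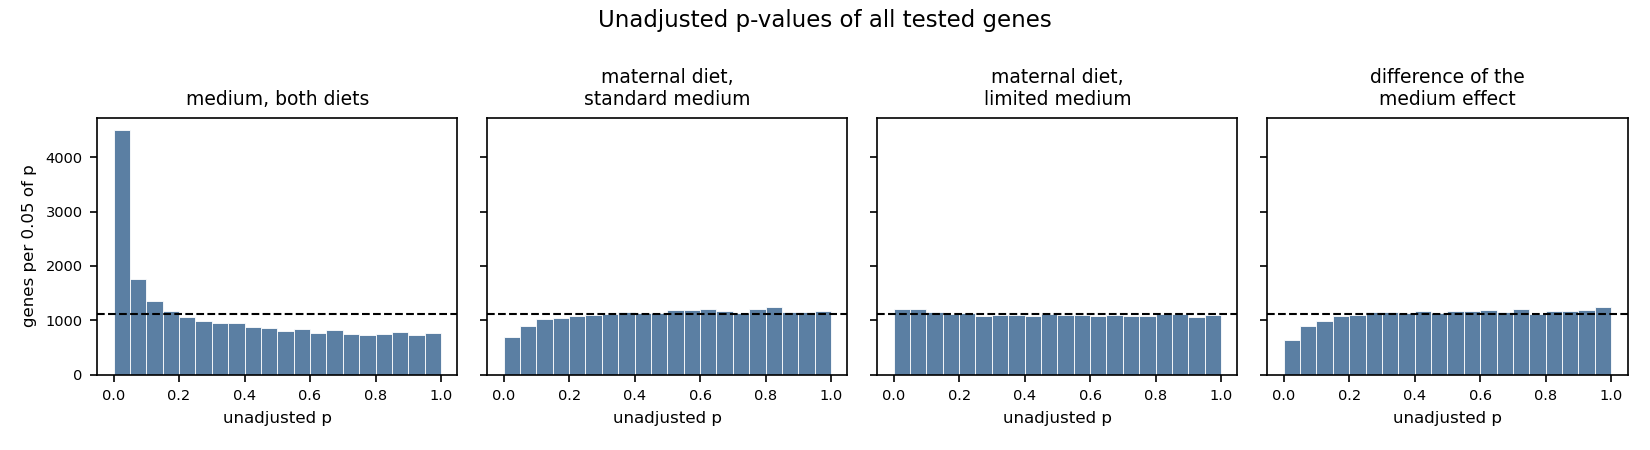
Number of genes (y axis) per 0.05 of unadjusted limma p (x axis) among 22180 genes in 4 comparisons, the dashed line being the 1109 genes expected in each bin by chance. The first bin held 4504 genes for the medium over both diets, 697 and 1206 for maternal diet in standard and limited medium and 643 for the difference of the medium effect.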

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

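The tests of the length bias of single arrays, of the spread between cultures, of cultures 16 and 20 (both tests) and the list values without single cultures, except those of the integrated stress response, were chosen after the result was seen, while the other tests below were set out before their result was seen.

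In control limited arrays, culture 11 lay far below the other 5 cultures for several genes of the stress response. Its log2 signal was 8.17 for Sdf2l1, 10.99 for Herpud1, 7.08 for Trib3, 7.33 for Chac1, 7.17 for Sesn2 and 8.19 for Hmox1, and its list mean was 8.29 for the integrated stress response and 7.59 for fatty acid synthesis. Chance flags about 1 in 20 groups by the gap of the farthest array to its neighbour, and without the 5 genes chosen after their values were seen, 45 were found over 728 such groups of named genes and lists, which share arrays and are not independent, against 36 expected by chance.

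In undernourished standard arrays culture 9 stood apart from the other cultures at 9.97 for Cox7a1, 6.85 for Sesn2, 9.64 for P4ha1, 11.05 for Ddx5, 7.84 for Ciao3, 8.72 for Grhpr, 9.54 for Ep400 and 8.58 for the cholesterol synthesis list. Culture 4 did so at 8.93 for Plagl1, culture 8 at 7.13 for Cdsn and culture 20 at 5.49 for Trim46. In undernourished limited arrays the array far from the others was culture 20 for Herpud1 (11.00), Hspa5 (9.99) and Hdac9 (6.63), culture 8 for Arntl (8.15) and the autophagy list (9.13), culture 4 for Map1lc3a (9.27) and Slc5a5 (6.22), culture 9 for Tmem175 (6.78) and culture 12 for Ddx5 (11.32). In control standard arrays it was culture 16 for Hspa1b (8.40), Hspa1a (8.38) and Gca (6.63), culture 5 for Irs2 (6.07), culture 10 for Nxt2 (5.97) and culture 15 for Glo1 (8.91). In control limited arrays it was culture 24 for Pfkfb3 (6.51), culture 15 for Vcam1 (6.19) and Leng8 (9.18), and culture 16 for the cell cycle list (6.31) and the inflammatory list (6.53).

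Collagen and fibroblast transcripts were high in control culture 16 and undernourished culture 20, and glial transcripts in culture 20. Dcn lay at 7.33 and 9.07 in the standard and limited arrays of culture 16 and at 5.91 and 7.53 in those of culture 20, and the fibroblast list at 6.28 in limited arrays of culture 16 and at 5.91 and 6.05 in those of culture 20. In culture 20, Col1a1 lay at 11.76 and 11.29, Cdh19 at 10.39 and 9.42, the glial list at 7.43 and 7.31, and in limited medium the collagen list at 9.17 and the smooth muscle list at 7.47. On the glial list culture 16 (5.92) lay next to control culture 24 (5.86), which also carried Cdh19 at 5.99. Maternal diet is argued against, since the cultures belong to 2 diets. Cells of other types in these cultures stay open as a candidate explanation that the data cannot decide: the collagen and glial means of these 2 cultures are the highest, but the cultures were picked by them.

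The response of some lists to limited medium differed between maternal diets by camera at the preset correlation. The mean difference, undernourished minus control, was 0.41 for the integrated stress response, 0.31 for endoplasmic reticulum chaperones, -0.12 for oxidative phosphorylation, -0.22 for the cell cycle list, 0.16 for ribosome biogenesis and 0.23 for hypoxia targets. Without undernourished culture 4 the cell cycle value was -0.04, without culture 9 oxidative phosphorylation was -0.06 and hypoxia targets 0.15, and without culture 20 the chaperones were 0.51. For the integrated stress response a single culture is argued against as the whole source, since the difference was still 0.233 without undernourished culture 9 (lowest), 0.26 without control culture 11 and 0.57 without control culture 5 (highest). Spread between cultures may account for it, with an exact two-sided permutation p of 0.258. An effect of the maternal diet also stays open.

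Among 11044 genes with a known genomic span and a level at or above the median, short genes rose more often in limited medium than long ones, with a Spearman rho across genes, which are not independent replicates, of -0.246 between span and log2 difference. A length bias of single arrays unrelated to the medium is argued against by the array slopes, which differed between media (permutation p = 0.00583). The shuffles ignored the culture number, and the trend had first been seen on the same arrays. In control cultures 24 and 16 and undernourished culture 9 the slope was not lower in limited medium. The trend is argued against as the source of the chaperone calls, since 17 of 19 chaperones passed after it was removed. A lower share of nuclear RNA in the limited-medium extracts may contribute: within groups the slopes correlated with the mean of 11 nuclear-retained RNAs over 24 arrays (Pearson r = 0.578, permutation p = 0.00503; Spearman rho = 0.534; r = 0.529 without the 2 arrays farthest from the median). Of these RNAs 3 fell, namely Malat1, Airn and Leng8, and 3 are also in the imprinted list and 1 in the sex-linked list. The spans of these RNAs were not taken into account. The correlation therefore cannot tell a lower nuclear share from the length trend acting on these RNAs. A biological effect of the medium on long genes was not tested and stays open.

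Clusters outside the gene tests also differed between media. Of 1814 clusters with several symbols 61 passed over both diets, 3 in control and 10 in undernourished cultures, and of 16010 clusters not named here 93 passed over both diets, 24 higher and 69 lower, and 2 in control cultures.

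Random regroupings were compared with the real one, 100 in each case with the real one included. For the medium, 1 of 100 gave as many genes, the real one itself. This held for the 1517 genes over both diets (highest other 24), the 76 in control cultures (53) and the 324 in undernourished cultures (195). Chance is argued against for these counts at 1 of 100, the lowest share that 100 regroupings can give. The comparison concerns the counts and does not exclude chance for single genes. For maternal diet and for the difference of the medium effect the real count was 0 with limma, with 697, 1206, 791 and 643 genes at an unadjusted p under 0.05 in standard medium, limited medium, over both media and for the difference. With a real count of 0, each regrouping gives as many whatever the data (100 of 100), so the comparison decides nothing there, and the highest other counts were 39, 28, 1 and 1 in the same order.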

How the results depend on the processing

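The tests without cultures 16 and 20, of lists without each culture, with a length trend removed and by permutation of lists were chosen after the data were seen; the others were planned. No named gene reversed under any alternative run. Among lists called by camera, medians turned with 1 culture left out for the cell cycle difference between diets (-0.30 to 0.021, highest without undernourished culture 4) and for fatty acid synthesis in undernourished cultures (-0.19 to 0.054, highest without culture 12). With the length trend removed, the glycolysis median over both diets, a list not called, went from 0.0014 to -0.0199. Over all pairs of a named gene and an alternative, 3884 kept their side of the threshold, 481 lost it and 5 gained it. With the culture number as a block the counts were 2597 for the medium over both diets, 551 in control and 1007 in undernourished cultures. The block ended 0 and added 5 list calls by camera at the preset correlation: insulin and IGF signalling over both diets (adjusted p = 0.0414) and in undernourished cultures (0.0257), contractile genes in control cultures (0.00301), and collagens in undernourished cultures (0.007) and for the difference between diets (0.000516). These had adjusted p = 0.464, 0.376, 0.457, 0.651 and 0.737 with an estimated correlation. Pairing by number is not established by the labels or by every pair: deviations of both arrays of a number correlated above 0.1 in 10 of 12 cultures (median 0.288, lowest -0.0497). Each array's deviations from its group mean were compared only with those of arrays of the same diet in the other medium. As a hint from the data, 20 of 24 arrays correlated best there with the array of their own number. Each array had 6 candidates, so some matches can arise by chance, but chance alone would give far fewer than 20. The arrays of undernourished cultures 9 and 12 correlated best with another number. The main tests of the medium did not use the number. In the signal itself the highest correlation, 0.995, joined the standard arrays of control culture 11 and undernourished culture 12. The consensus correlation was 0.194. At an adjusted p under 0.1 the counts were 2325, 253 and 622, and with a difference of at least 0.5, 267, 47 and 192. Array quality weights gave 275 in control and 571 in undernourished cultures and 1 for maternal diet in limited medium. Only genes at or above the median level gave 149 in control cultures. With only the groups compared, where fewer arrays entered the fit, control and undernourished cultures had 59 genes each. Of the main calls, 76 and 324, this fit kept 35 and 59. Without cultures 16 and 20 the counts were 115, 494 and, for maternal diet in limited medium, 2. Leaving out 1 culture in turn gave 991 to 1603 over both diets, 10 to 162 in control cultures, 51 to 469 in undernourished cultures and 0 to 2 for maternal diet in limited medium. With an estimated inter-gene correlation 0 lists passed in each of the 7 comparisons, and by permutation of arrays or cultures 8 passed for the medium over both diets. The exact permutation gave 0 in the other comparisons. Its smallest attainable p, 0.00216, was reached only for the medium in undernourished cultures; elsewhere the smallest unadjusted p was 0.00866 for the medium in control cultures, 0.0714, 0.0173 and 0.0216 for maternal diet in standard medium, limited medium and over both media, and 0.0498 for the difference, so the camera calls there were not kept by this test. Leaving out 1 culture gave 5 to 8 lists for maternal diet in standard medium, 3 to 9 in limited medium and 4 to 11 over both media. Beyond thresholds and numbers of arrays, the cause was not tested. The fit with only the groups compared is the same fit for the medium over both diets, and the list test with a block was not run for maternal diet. Signal near background limits what dim genes can show.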

Other observations

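The tests of gene classes by name were chosen after the data were seen. Small nucleolar RNAs, 73 genes, averaged 8.31 ± 0.40 in control standard, 8.77 ± 0.25 in control limited, 8.01 ± 0.42 in undernourished standard and 8.31 ± 0.40 in undernourished limited arrays (log2 signal, SD, n = 6). The difference between media in control cultures was 0.46 (exact permutation p = 0.0325, adjusted p = 0.216 over 16 tests) and that between maternal diets in limited medium was -0.46 (exact permutation p = 0.0455, adjusted p = 0.216). For 60 ribosomal protein genes the difference between media in control cultures was 0.14 (exact permutation p = 0.039, adjusted p = 0.216). No class passed after adjustment, and microRNA and receptor genes were the other classes tried.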
